A study of Mus musculus with 2 samples.

How the data were processed

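Total RNA from dorsal skin was measured on 2 Affymetrix Mouse Gene 2.0 ST arrays, 1 for the saline control and 1 for FGF18, with groups taken from the sample labels. The strain, sex and age are the same in both labels. Per the labels, RNA was extracted with Trizol and labelled with biotin by the GeneChip WT PLUS kit. Per the submitters' processing notes, the authors used Affymetrix Expression Console and RMA, a procedure that corrects background, normalizes arrays to a shared distribution and summarises the probes of a transcript cluster. Software versions are not given in the sources used here. The deposited values are intensities on a linear scale, as judged from the values, which ran from 1.39 to 11488 in saline and from 1.44 to 11532 after FGF18, with medians of 14.0 and 13.8. Arrays have no read depth, and having 1 per group limits the precision.

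The table held 41345 transcript clusters. The platform annotation gave 1 gene symbol to 23521 of them, several to 1814 and none to 16010. Only clusters with 1 symbol were used for genes, and clusters of the same symbol were averaged on the log2 scale, which gave 22180 genes, 1082 of them from more than 1 cluster. Of these clusters 23328 matched the mouse gene table (assembly GRCm38.p6) by Entrez identifier, all with the same symbol, and the other 193 kept the annotation's symbol. Values of 2026 clusters were exactly equal on both arrays. Trp53, Ccnb1 and Krt5, which were to be named whatever their values, had no cluster with a single symbol and were not analysed here.

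The design written before the data were examined took the values to be log2. They were linear, so log2(intensity + 1) was used, an option fixed at the same time, with a pseudocount of 16 as its alternative. For each gene the difference was FGF18 minus saline. The main counts took genes whose mean over both arrays was at or above the median over genes (4.15) and whose difference reached 2-fold, with 1.5-fold beside it. No p-value, standard error or spread between samples can be had from 1 array per group. Over 311 symbols with at least 2 clusters above that level, differences from separate clusters correlated with r = 0.47, and the standard deviation of a cluster's difference from this source was 0.25. This covers disagreement between probe sets and not variation between animals. The files used here hold no detection call, and the rule that a named gene below its array's median is given without a fold was set after the values were seen. As a check of the sex labels, Xist read 6.42 and 7.74 in saline and FGF18, and the Y-linked genes Eif2s3y, Kdm5d and Uty read 94.1 and 148, 34.8 and 39.9, and 58.6 and 55.5. Ddx3y had no cluster with a single symbol and was not used here.

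Before the data were examined, 24 gene lists and 18 marker lists of cell types and skin layers were fixed, and the report gives the result of each. A list's result is the median difference over its measured members and the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles from 2.5 to 97.5 form the central 95%. The list of red blood cell markers had 1 measured member and no percentile. Intervals of list medians are 95% order-statistic intervals over members, or the range of members where there were under 6. Named genes followed a rule fixed at the same time. It took the 12 largest differences in each direction among counted genes, without predicted genes, RIKEN, microRNA, small nucleolar, olfactory and vomeronasal receptor and immune receptor genes, and with at most 3 of one keratin or similar family. It also took the 2 highest and 2 lowest members of each list among those at or above the median level, and a fixed set around FGF signalling, p53, proliferation and keratins. Krt10, Krt17, Krt75, Tchh and Slc4a1 in the report, and genes of the closing observations outside this rule, were chosen after their values were seen. A further 8 lists, also chosen after the values were seen, are given only with the closing observations. They hold late cornified envelope, small proline-rich, filaggrin-like, kallikrein, barrier lipid, interleukin-1 family, wound keratin and muscle atrophy genes.

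Alternatives were no filter or a filter at the 75th percentile, a 1.5-fold threshold, centring on the median difference, subtraction of a loess trend of difference on mean (span 0.3), the brightest cluster in place of the average, clusters with several symbols counted under their first symbol, and a pseudocount of 16. For lists they were members at or above the median level, the mean in place of the median, leaving out the farthest member or members shared with other lists, and random lists matched on the saline array or not matched. Log2 with no pseudocount was added after the data were seen, as were percentiles under each alternative for values, clusters, members and the mean, against random lists of the same size drawn from the same values.

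The steps were tested on simulated data for 11090 genes with noise of standard deviation 0.3, in which 200 genes were changed 4-fold. A tilt of the difference with intensity was also added, with a slope of 0.048 before loess subtraction. All 100 raised genes were counted as 2-fold higher, but only 59 of 100 lowered genes were counted as 2-fold lower, because a 4-fold drop can take a gene's mean below the level filter. The count of lower genes in the report leaves out such genes. Of unchanged genes, 13 passed 2-fold through noise and this tilt. Of 400 simulated unchanged lists of 12 genes, 5.75% lay outside the central range, and all lists shifted by 0.5 lay above it. These simulated lists used differences after loess subtraction, whereas the main percentiles of the report use differences without it. Their genes were drawn at random from the same differences as the random lists, so the share outside was largely set in advance. It does not cover real lists, whose genes can vary together. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.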

Results

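Gene expression was measured in back skin of male BALB/cAJcl mice, an albino strain, at 7 weeks of age, on 1 array from a saline control and 1 array from FGF18 treatment. FGF18 is a fibroblast growth factor that the series title links to the resting phase of the hair cycle and to radioresistance of hair follicles. Hair had been removed to start the growth phase (anagen), and 100 µg of FGF18 in saline with heparin at 5 µg/µl was injected into the peritoneum 6 days later. A whole-body γ-ray dose of 6 Gy followed 24 h after the injection, and skin was collected 4 h after that. The labels spell out this course for FGF18 and call the other sample a saline control. They do not say whether the control was irradiated or received heparin, or how many mice gave each sample, so a difference between the arrays cannot be assigned to FGF18 alone. The comparison asks how the transcripts of regrowing skin differed after FGF18. With 1 array per group there were no replicates and no significance test, so each difference below compares these 2 arrays. Differences are FGF18 minus saline on the log2(intensity + 1) scale, and on that scale folds of dim genes are understated. A named gene whose value lay below its array's median intensity is not shown above background there, so its intensities are given and no fold.

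Many of the transcripts with the lowest differences on the FGF18 array belong to the cornified epidermis. Krt1, a keratin of suprabasal epidermis, read 4003 in saline and 512 after FGF18, which is 7.80-fold lower, and Hrnr, which encodes a cornified envelope protein, was 5.83-fold lower. Both were bright on both arrays, and with a pseudocount of 16 they were 7.61-fold and 5.63-fold lower. Stfa3, a stefin A protease inhibitor gene, read 348 in saline and 7.78 after FGF18, and the keratin genes Krt6b and Krt16, known from wounded skin, read 256.0 and 145 in saline and 12.1 and 12.4 after FGF18. The cornified envelope genes Rptn and Lce1e read 88.0 and 100.2 in saline and 8.33 and 10.7 after FGF18. These 5 genes lay below the FGF18 array's median of 13.8, and Xist, a transcript of female cells, read 7.74 on this array from male skin. They are therefore not shown above background after FGF18. Sprr1b, another cornified envelope gene, was 8.58-fold lower, the interleukin-1 family cytokine genes Il1f8 and Il1f9 9.26-fold and 5.96-fold lower, the secreted epidermal protein gene Slurp1 8.70-fold lower and the kallikrein protease gene Klk9 5.94-fold lower. With a pseudocount of 16 these genes were lower by folds from 4.01 (Klk9) to 5.78 (Slurp1).

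Fewer transcripts were higher on the FGF18 array, and by less. The chemokine gene Cxcl13, which attracts B cells, was 6.62-fold higher (23.8 in saline, 163 after FGF18), and the acute-phase gene Saa3 was 5.04-fold higher. Pdk4, a kinase that restrains glucose oxidation, was 3.09-fold higher, and the muscle ubiquitin ligase genes Fbxo32 and Trim63 were 2.88-fold and 2.71-fold higher. The imprinted zinc finger gene Peg3 was 2.70-fold higher, the muscle small heat shock protein gene Hspb7 2.46-fold and the RNA helicase gene Ythdc2 2.44-fold, and the zinc finger gene Zfp781 read 12.1 in saline and 33.1 after FGF18. The hair keratin gene Krt31 was 2.34-fold higher, and the taurine transporter gene Slc6a6 and the sorting nexin gene Snx30 were each 2.29-fold higher. With a pseudocount of 16, Hspb7, Ythdc2, Krt31 and Snx30 were under 2-fold, at 1.99, 1.91, 1.76 and 1.80, as was Zfp781, and the other 7 of these 12 genes were at least 2-fold higher. Cxcl13, Saa3, Peg3 and Trim63 were then 4.50-fold, 3.18-fold, 2.23-fold and 2.22-fold higher.

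Among 11090 genes at or above the median level, 42 were at least 2-fold higher and 183 at least 2-fold lower on the FGF18 array, so 81.3% of these genes lay on the lower side. With a pseudocount of 16 these counts were 13 and 111. At 1.5-fold the sides were closer, with 404 genes higher and 514 lower. Across all 22180 named genes the arrays correlated with a Pearson r of 0.974 on the log2 scale and a Spearman rho of 0.974. Genes are not independent replicates, so these coefficients describe only how alike the arrays were.

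**Figure D1:**
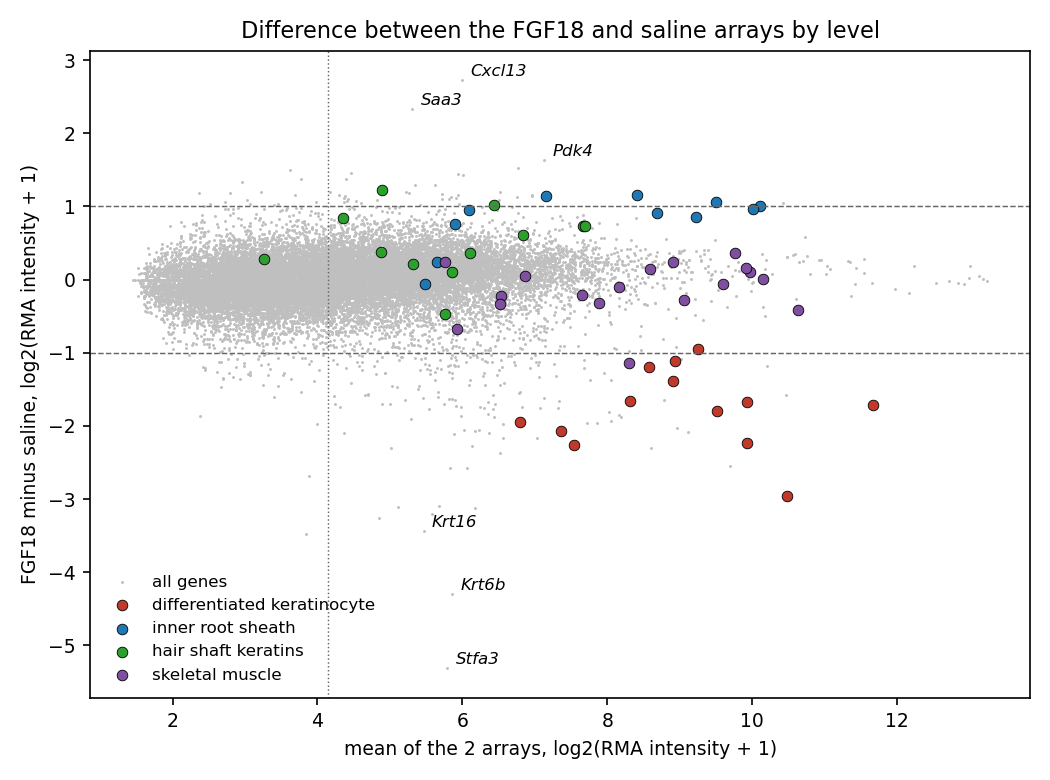
Each point is a gene, with its mean over both arrays on the x axis and its FGF18 minus saline difference on the y axis, both in log2(RMA intensity + 1). Colours mark 4 of the gene lists, dashed lines mark 2-fold and the dotted line the median level of 4.15. The 13 differentiated keratinocyte genes lie below 0, 10 of 11 inner root sheath genes lie above it, and skeletal muscle genes lie on both sides.

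Markers of differentiated keratinocytes were lower on the FGF18 array without exception. All 13 measured members were lower, 12 of them at least 2-fold, and the median difference was -1.71, below all 10000 random lists of the same size and expression. Casp14, a protease of the cornified layer, had a difference of -2.26, the keratin gene Krt10 one of -1.71, the suprabasin gene Sbsn one of -1.12 and the loricrin gene Lor one of -0.95. Markers of basal keratinocytes did not share this. Their median difference was 0.09 over 6 members (-0.02 after subtraction of the intensity trend), with Col17a1 at 0.39, Itgb4 at 0.37 and Krt14 at -0.81, and it lay at percentile 45.6 of its random lists. Many basal markers are also made by the outer root sheath of the follicle.

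Genes of the growing hair were higher on the FGF18 array. Of 11 inner root sheath genes, which encode the sleeve that moulds the hair, 10 were higher, 4 of them at least 2-fold, and the median difference was 0.96. Krt28 went from 228 in saline to 508 after FGF18 (difference 1.16), Krt72 had a difference of 1.14 and Tchh, the trichohyalin gene, one of 0.96, whereas Gata3 had one of -0.06. Of 12 hair shaft keratins 11 were higher, with a median of 0.50. Krt31 and Krt82 led them at 1.22 and 1.02, and Krt81 was lower at -0.47. Both medians lay above all 10000 random lists. Keratin associated proteins, which cross-link the hair shaft keratins, had 35 members higher and 15 lower of 51, with a median of 0.18 that also lay above all random lists. Krtap8-1 stood at 1.16 and Krtap7-1 at 0.96. Over the 18 members at or above the median level the list's median was 0.30.

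**Figure D2:**
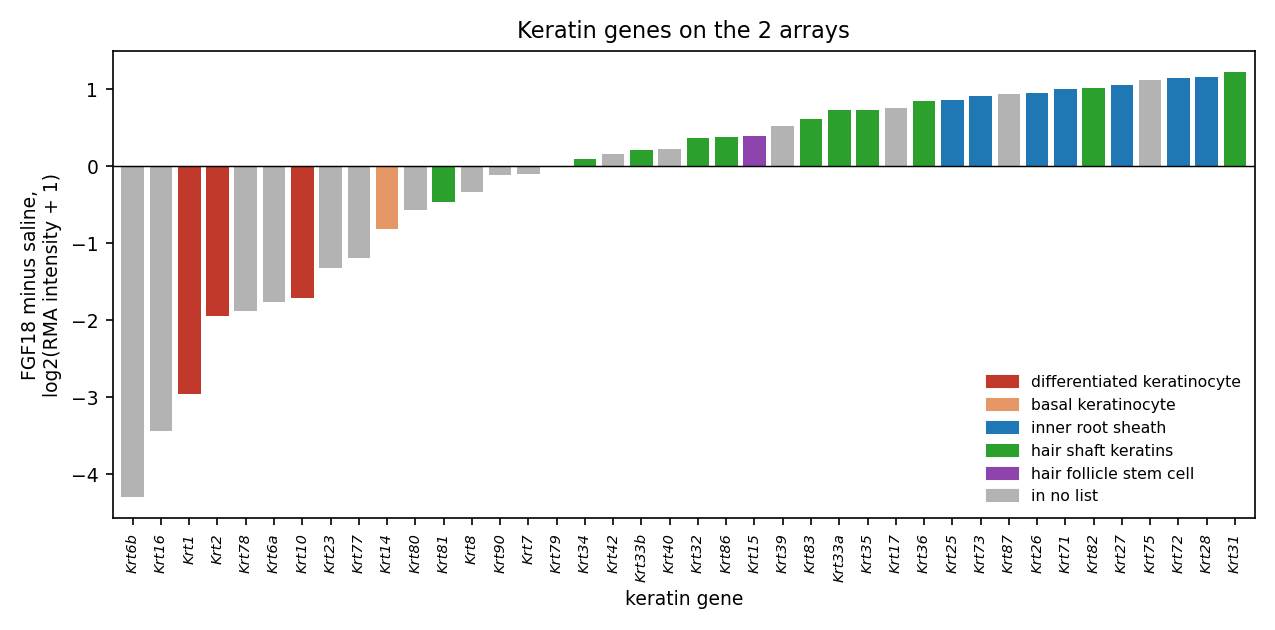
Bars give the FGF18 minus saline difference in log2(RMA intensity + 1) for the 40 keratin genes at or above the median level, coloured by the list that holds them. Krt1 at -2.96 and Krt31 at 1.22 are examples from either side, and the bars of Krt6b and Krt16 rest on values not shown above background after FGF18. Inner root sheath keratins lie at the high end with several hair shaft keratins, but the hair shaft keratins Krt34 at 0.10 and Krt81 at -0.47 do not.

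Over the 40 keratin genes in that plot, 9 were at least 2-fold lower and 7 at least 2-fold higher. Krt75, a keratin of the follicle's companion layer, had a difference of 1.12. Krt17, which is expressed in the outer root sheath and in wounds, had one of 0.76.

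Genes of hair matrix regulators and of several signalling pathways lay mostly on the same side as the hair keratins. Of 10 hair matrix transcription factors 7 were higher and 2 lower, with a median of 0.53 at percentile 99.99. Hoxc13, which drives hair keratin genes, had a difference of 1.09, Lef1, the effector of Wnt signals, one of 0.79, and Prdm1 one of -0.65. All 7 Hedgehog pathway genes were higher, with a median of 0.38 at percentile 99.42. The receptor and target Ptch1 stood at 0.74, the target Gli1 at 0.62 and the ligand gene Shh read 10.1 in saline and 11.1 after FGF18. BMP and TGF-beta genes had 13 of 16 members higher, with a median of 0.35 at percentile 99.98. This list holds ligands and their inhibitors, such as Bmp4 and Nog, so its direction does not give the activity of the pathway. The BMP targets Id3 and Id1 were at 0.53 and 0.51, while Id4 was at -0.95. Dermal papilla markers, from the mesenchyme that instructs the follicle, had a median of 0.29 over 10 members at percentile 98.76, led among brighter members by Wif1 at 0.78 and Fgf7 at 0.50. That placement rests on few members. Without the members shared with another list, Fgf7 and Fgf10, the median was 0.21 at percentile 89.6, and over the brighter members it was 0.22 at percentile 90.8. All 9 melanocyte markers were higher, with a median of 0.41 at percentile 99.93, among them Mlana at 0.81 and Tyr at 0.69.

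Wnt pathway genes and follicle stem cell markers lay within the central 95% of random lists, but not under every alternative. The Wnt list had a median of 0.20 over 15 members at percentile 94.5, with Nkd2 at 0.91 and Wnt10a at -0.65. The stem cell list had a median of 0.21 over 12 members at percentile 94.1, with the bulge keratin gene Krt15 at 0.40 and Cd34 at -0.23. With random lists not matched on expression, these percentiles were 98.46 and 98.38, outside that range. The Wnt percentile was also outside it with the brightest clusters, at 98.23, and over the brighter members, at 99.24 with a median of 0.31. The stem cell median was 0.12 after trend subtraction.

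Cell cycle genes differed by small amounts and not all one way. Of 40 genes of G2/M and mitosis, 27 were lower and 12 higher, with a median of -0.10 at percentile 0.10. The spindle genes Kif4 and Prc1 had differences of -0.48 and -0.47, and Sgo1 and Nuf2 differences of 0.49 and 0.47. The mitotic kinase gene Cdk1 stood at -0.40 and the proliferation marker Mki67 at 0.32. DNA replication and G1/S genes had 24 of 33 members higher, with a median of 0.16 at percentile 97.0. Mcm7, part of the replicative helicase, was at 0.48, Chaf1b at 0.53 and Tyms at -0.13. Ccnd1, the cyclin of G1, was at 0.52. The list of replication-dependent histone genes, taken by symbol prefix, had a median of 0.10 over 29 members at percentile 97.55. H2ac20 was at 0.32 and H1f2 at -0.19. The prefixes also took in H1f7, H1f8 and H1f10, so not every member is a replication-dependent gene. Over the 9 members at or above the median level, the histone median was 0.21 at percentile 89.4. Inhibitors of the cell cycle and quiescence genes had a median of 0.00, with 6 of 13 members higher and 6 lower. Cdkn2c and Cdkn2b stood at -0.52 and -0.47 and Cdkn2d at 0.29. No gene of these 4 lists reached 2-fold. Against unmatched random lists the G2/M percentile was 2.52 and the histone percentile 92.0, both within the central range, and the replication percentile 99.51, outside it. The histone list was also inside the range with the brightest clusters, at percentile 90.4.

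Targets of p53, the transcription factor that ionising radiation activates, were somewhat higher on the FGF18 array. Of 30 measured targets 23 were higher and 7 lower, and the median of 0.28 lay at percentile 99.94. Sulf2 and Psrc1 stood at 0.85 and 0.73, and the cell cycle inhibitor gene Cdkn1a at 0.23. The kinase gene Plk3 was at -0.91, Perp at -0.38 and Mdm2, which encodes the ligase that degrades p53, at -0.12. Ccng1 and Rrm2b were near equal on both arrays, at 0.007 and 0.003, and Sesn2 was at -0.24. The labels do not say whether the control was irradiated, so these differences cannot be assigned to radiation or to FGF18. DNA damage signalling and repair genes had a median of 0.11 over 28 members at percentile 80.1, with Mdc1 at 0.75 and Chek1 at -0.28. Apoptosis effectors had a median of 0.18 over 15 members at percentile 96.6, with Apaf1 at 0.49 and Bad at -0.14, while Bik read 13.8 in saline and 24.7 after FGF18. The apoptosis percentile was 99.33 after trend subtraction, outside the central range, and 65.0 over the brighter members, whose median was 0.10. The p53 target median was 0.19 after trend subtraction, at percentile 99.92.

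FGF pathway genes stayed within the central range. The FGF ligand and receptor list had 9 members higher and 8 lower, with a median of 0.08 at percentile 81.3, and without members that other lists hold the median was -0.07 at percentile 19.4. Fgf18 itself read 21.6 in saline and 25.4 after FGF18. Because the protein was injected, its transcript does not check which sample received it. The receptor genes Fgfr1 and Fgfr2 stood at 0.56 and 0.57, Fgfr3 at -0.18 and Fgfr4 at -0.58. Feedback genes of FGF and ERK signalling had 10 of 14 members higher, with a median of 0.12 at percentile 83.6 (0.06 after trend subtraction). The ERK phosphatase gene Dusp6 was at 0.50, Dusp5 at -0.25, and Spry4 had equal intensities of 15.8. Immediate early genes had a median of 0.08 over 18 members at percentile 54.1, with Egr1 at 0.49 and Klf4 at -0.55.

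Among stress and immune genes, the glucocorticoid response list stood apart. Of its 10 genes 8 were higher, with a median of 0.40 at percentile 99.96. Pdk4 was at 1.63 and Zbtb16 at 0.87, while Errfi1 and Sgk1 were at -0.45 and -0.37. Interferon-stimulated genes had 15 of 19 members higher, with a median of 0.15 at percentile 97.46, just inside the central range. Irf7 was at 0.48 and Stat2 at -0.59, and Isg15 read 12.6 in saline and 23.2 after FGF18. With random lists matched on the saline array the interferon percentile was 97.6, outside the range. The median was 0.27 over the brighter members and 0.07 with a pseudocount of 16. Inflammatory cytokines and NF-kB targets had a median of 0.15 over 19 members at percentile 96.5 (98.58 after trend subtraction, and a median of -0.08 over the brighter members), from Il1a, an epidermal cytokine, at -1.64 to Saa3 at 2.33. Heat shock genes had a median of -0.02 over 10 members at percentile 14.7, with Hspa1b at -0.56 and Hsph1 at 0.31. Circadian clock genes had a median of 0.02 over 15 members at percentile 32.6 (-0.03 after trend subtraction), with Cry2 at 0.37 and Ciart at -0.36. Reference genes had a median of 0.02 over 11 members at percentile 22.7 (-0.07 after trend subtraction), but ranged from B2m at -0.49 to Tbp at 0.69.

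Markers of the dermis, fat, muscle and other cells gave no common shift. Fibroblast markers had 5 of 9 members lower and a median of -0.25 at percentile 0.55, with the matrix genes Lum and Dpt at -0.95 and -0.69 and Dcn at 0.42. The fibroblast median was -0.12 without Lum, its farthest member, and also with the brightest cluster of each gene, at percentiles 4.67 and 4.51, inside the central range. Skeletal muscle markers had 10 of 18 lower and a median of -0.08 at percentile 1.51, with Casq1 at -1.14 and the myosin gene Myh1 at 0.36. With no matching the muscle percentile was 13.5, inside the central range. Adipocyte markers had a median of -0.09 and a mean of 0.10 over 11 members, at percentile 8.58 (median 0.02 over the brighter members), with the lipid droplet gene Plin4 at 1.02 and the resistin gene Retn at -0.55. Smooth muscle and pericyte markers had a median of 0.24 over 7 members at percentile 94.6, with Acta2 at 0.33, and of 0.15 after trend subtraction. Endothelial markers had a median of 0.10 over 10 members at percentile 85.2, with Pecam1 at 0.21 and Cdh5 at -0.66, and the median was -0.26 over the 4 brighter members and 0.21 at percentile 97.6, outside the central range, without the farthest member. Sebaceous gland markers had a median of 0.00 over 7 members at percentile 33.4, with Awat1 at 0.11 and Elovl3 at -0.28. Macrophage markers had 9 of 11 members higher and a median of 0.17 at percentile 94.2, with Lyz2 at 0.57 and C1qa at 0.51. Over the 6 brighter members the macrophage median was 0.36 at percentile 99.11, and after trend subtraction the percentile was 98.0, both outside the central range.

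Lymphoid, mast and nerve markers were mostly dim. T cell markers had a median of -0.12 (percentile 20.6), B cell markers one of 0.04 (percentile 75.4), mast cell markers one of 0.00 (percentile 69.6) and neutrophil markers one of -0.11 (percentile 24.9). Langerhans and dendritic cell markers had a median of -0.04 (percentile 30.9) and one of 0.27 over the 3 brighter members (percentile 84.3), with Cd207 at 0.38, and Schwann cell markers one of -0.13 over 4 members (percentile 24.1). Slc4a1, the single measured red blood cell marker, read 10.4 in saline and 6.43 after FGF18.

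**Figure D3:**
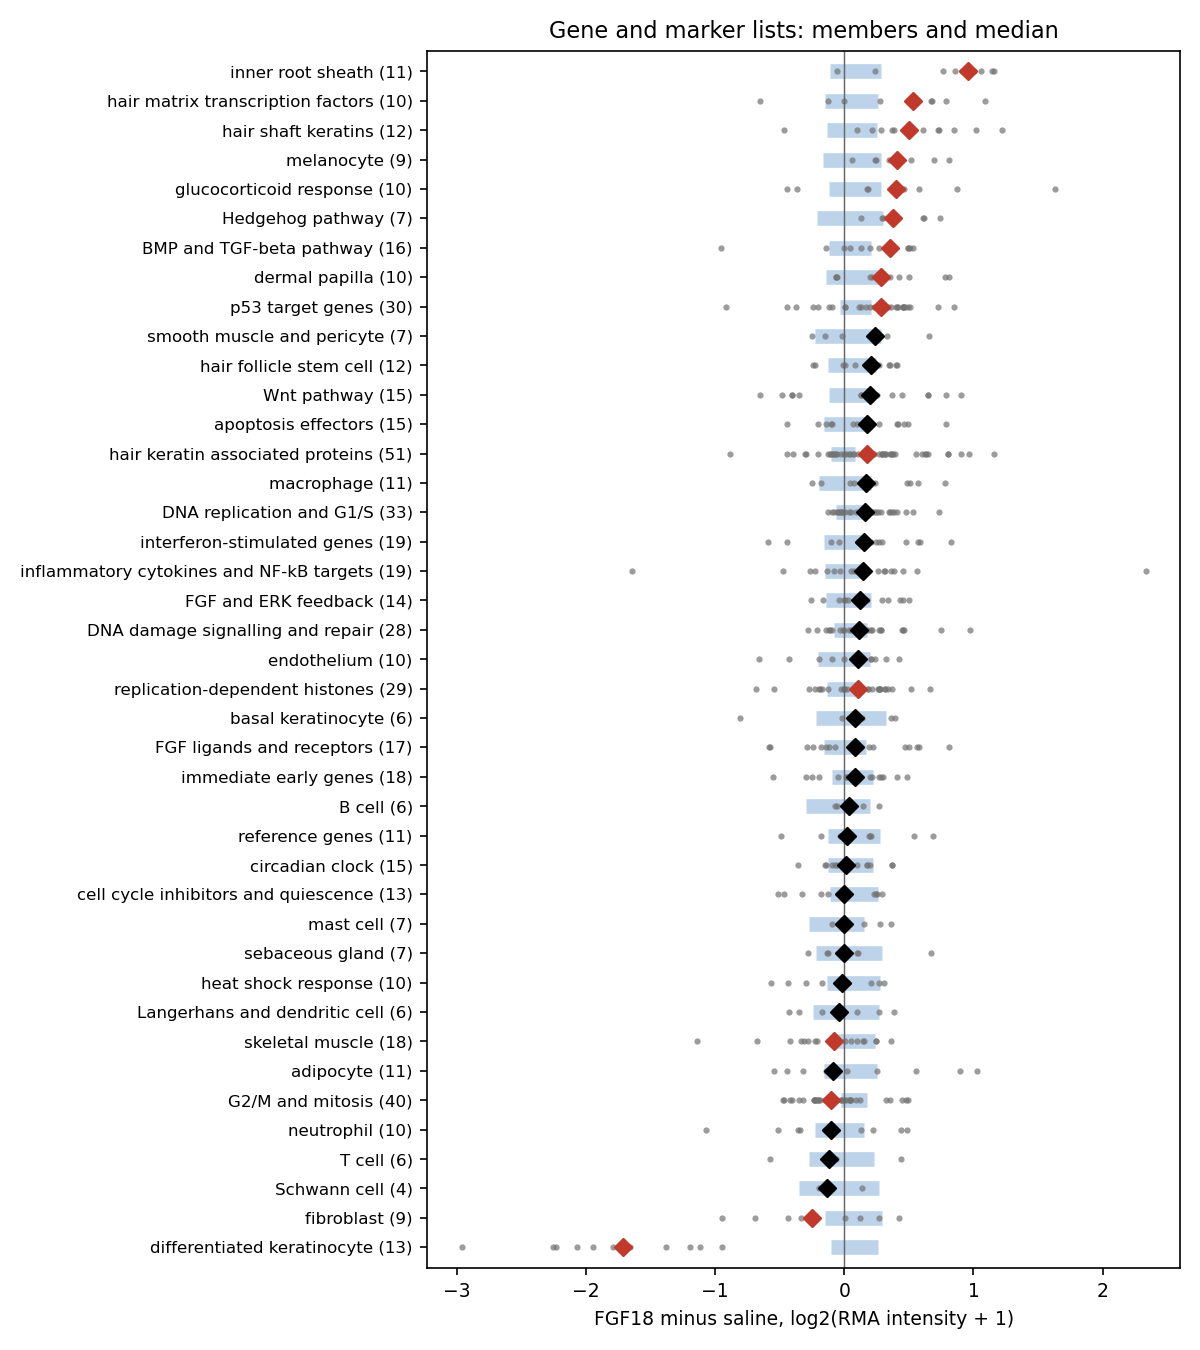
Each row is a gene or marker list with its number of measured members. Small points are members and diamonds the list's median, as FGF18 minus saline differences in log2(RMA intensity + 1), and the blue band holds the central 95% of medians of 10000 random lists matched on expression. Red diamonds mark the 15 lists outside their band, from differentiated keratinocytes at -1.71 to the inner root sheath at 0.96.

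Of the 41 lists with at least 3 members, 15 lay outside the central 95% of their random lists, 11 above and 4 below, where 2.05 would lie outside if genes were independent. Of these 15, 10 stayed outside under every alternative for which a percentile was computed, and G2/M, histones, fibroblasts, dermal papilla and skeletal muscle did not. Genes of a tissue layer vary together even between untreated animals, so these percentiles describe the 2 arrays and not an effect of treatment. Probes of near-identical families, such as the stefin A, Krt6, late cornified envelope and keratin associated protein genes, can bind each other's transcripts, so single members of these families are uncertain. A pseudocount of 16 moved some genes of the naming rule, given here as differences, by more than the disagreement between probe sets (0.25). Hoxc13, Plin4, Krt31, Il1a, Fgfr4 and Lum moved to 0.71, 0.76, 0.81, -1.16, -0.32 and -0.60. Saa3 and Sprr1b moved to 1.67 and -2.34.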

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

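All tests of explanations in this part were chosen after the results were seen.

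Transcript clusters without a gene symbol, which enter no comparison of the report, included 175 that were at least 2-fold higher on the FGF18 array and 142 at least 2-fold lower, among 5365 at or above the median level of named genes. These are 3.26% and 2.65% of them, against 0.379% and 1.65% of named genes, and the clusters with higher values hold 167 distinct pairs of values. The shares are not alike in kind, because unnamed clusters were taken singly while 1082 of the 22180 genes average several clusters. How noisy the unnamed clusters are was not examined, so these shares do not show that unnamed transcripts differed more.

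Differentiated keratinocyte genes were lower on the FGF18 array, with a median difference of -1.71. A tilt between the arrays with intensity is argued against, because the median was -1.81 after the loess trend was subtracted. A smaller share of epidermis in the FGF18 skin piece cannot be told apart from lower expression per cell. The basal keratinocyte median was 0.0859, but follicle genes were higher and the outer root sheath shares these basal markers, so a gain there could hide a loss. Treatment with FGF18, a difference between animals in healing after depilation and the site of the skin piece also stay open, since each array is its own group.

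Hair follicle genes were higher on the FGF18 array, with an inner root sheath median of 0.96. A loss of abundant epidermal transcripts would raise all other genes alike, so follicle genes would lie no higher than other markers. This is argued against by the gap to 55 markers of fibroblasts, skeletal muscle, endothelium, fat and smooth muscle. Their pooled median was -0.0187 (95% interval over members -0.194 to 0.145), and 10 of 11 inner root sheath genes lay above it. Only the gap counts here, because RMA gave both arrays a shared distribution, which holds the level of most genes equal. Macrophage, dermal papilla and melanocyte markers, left out of this pool, had medians of 0.17, 0.29 and 0.41, which also lay below the inner root sheath median. The pool took in fibroblast and skeletal muscle markers, already seen to lie below their random lists, so the size of the gap depends on this choice. The interval takes members as independent and does not cover variation between animals. A tilt with intensity is argued against by the inner root sheath median of 0.851 after trend subtraction. An animal or skin piece further into anagen, or with more follicles, may give the same picture as an effect of FGF18, and neither was tested.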

How the results depend on the processing

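The alternatives were chosen before the data were examined, except the values with no pseudocount and the percentiles under other values, clusters or members. The count of genes at least 2-fold higher was 42 and moved to 27 with the filter at the 75th percentile and to 13 with a pseudocount of 16, and the count at least 2-fold lower was 183 and moved to 111 with that pseudocount. At 1.5-fold the counts were 404 and 514, by construction. Loess subtraction gave 33 and 221, and the counts without a filter were 57 and 236. Of 364 recomputed list medians 362 stayed within the interval of the main median over members. The others were the keratin associated proteins, 0.296 over brighter members against 0.18, and the interferon-stimulated genes, 0.0732 with a pseudocount of 16 against 0.15. Staying within these intervals is a loose criterion, because many are wide. The endothelial median moved from 0.10 to -0.26 over brighter members and still lay within its interval of -0.43 to 0.32. Some recomputations could not move. Centring left the 41 medians and the 41 percentiles as they were, because the median difference over genes was 0. Leaving out shared members changed nothing for lists that share none. The median of 8 lists changed sign under an alternative, and none of these lay outside its central range in the main setting. Of 406 recomputed percentiles 366 kept their side of the range. In 19 a list outside it moved inside (G2/M, histones, fibroblasts, dermal papilla and skeletal muscle), and in 21 a list inside it moved outside (replication, apoptosis, follicle stem cells, Wnt, interferon, inflammatory, endothelium and macrophages). Named genes kept their difference within the probe-set spread of 0.25 in 665 of 692 recomputations, and 26 of the 27 others came from the pseudocount of 16, which compresses dim genes by construction. Signal over background limits the dim lists most, such as T cell, B cell and mast cell markers. No paired analysis was possible because each group has 1 array.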

Other observations

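The gene lists of this part and the tests of explanations were chosen after the values were seen, and list percentiles here describe genes picked with knowledge of the result.

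Further epidermal gene families were lower on the FGF18 array, in part through genes that the differentiated keratinocyte list or the largest differences already held. Barrier lipid genes, which build the ceramides of the cornified layer, were lower in all 15 measured members, with a median of -0.90, and none of them was in an earlier list. Among them were the lipoxygenase gene Alox12b at -2.10 and the lipid transporter gene Abca12 at -1.81. Late cornified envelope genes were lower in 16 of 18 members, although 9 of the 18 lay below the median level, and skin kallikreins, proteases that shed the cornified layer, in 8 of 10 (median -0.85), with Klk5 at -2.17 and Klk10 at 0.73. Without Klk7 and Klk9, already named, the kallikrein median was -0.80 over 8 members. Filaggrin-like genes differed in direction. Hrnr, Flg and Flg2 of the epidermis stood at -2.54, -2.23 and -1.67 and Rptn was lower too, whereas Tchh and Tchhl1 of the inner root sheath stood at 0.96 and 0.24 and Crnn, an epidermal gene, at 0.64 (list median -1.67 over 7 members). Flg and Flg2 belong to the marker list, so this median restates it. Small proline-rich genes were lower in 8 of 12 members, with a median of -0.17 at percentile 4.43 (-0.07 without Sprr1b), and 8 of the 12 lay below the median level, where a drop is hard to measure. Among brighter members Sprr1b at -3.10 contrasted with Sprr1a at 0.56. In gene order on the GRCm38.p6 table, the epidermal differentiation complex was counted only from Pglyrp3 to S100a10. This stretch held 29 genes at or above the median level. Of these, 15 were at least 2-fold lower, 3 of them (Flg, Flg2 and Ivl) from the marker list. On the other side, 3 were at least 1.5-fold higher and 0 at least 2-fold higher.

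Several epidermal cytokine genes of the interleukin-1 family were lower on the FGF18 array. Over 10 family members the median was -1.67, with 6 at least 2-fold lower, among them Il1f5 at -2.28, Il18 at -1.75, Il1f6 at -1.70 and Il1a at -1.64. Without the 5 members that earlier lists or the largest differences held, the median was -1.70 over 5 members. Il33 stood at 0.05, and Il1b read 11.7 and 12.4 in saline and FGF18. Of 4 keratins known from wounds, Krt6a, Krt6b and Krt16 were at least 2-fold lower and Krt17 was higher at 0.76.

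The muscle atrophy genes Fbxo32, Trim63 and Pdk4 were among the 12 largest positive differences. A muscle atrophy list of 15 genes built around them had a median of 0.38 at percentile 99.96. Without these 3, the other 12 had a median of 0.06 at percentile 42.1. Without Foxo1 and Foxo3 as well, which a fixed list holds, the other 10 had a median of 0.23 at percentile 94.3. Both percentiles lie inside the central range, so the list's place outside it rests on Fbxo32, Trim63 and Pdk4. More muscle in the FGF18 skin piece is argued against by the skeletal muscle list, whose median was -0.0788. A glucocorticoid or fasting response in the FGF18 sample is offered as a hypothesis. No list here was built to measure fasting. Without Pdk4, the median of the other 9 glucocorticoid response genes was 0.36, at percentile 99.44 of matched random lists, although Sgk1 and Errfi1 were lower. The full list had already been seen at percentile 99.96, so this value restates that result and does not test the hypothesis. Whether a glucocorticoid or fasting response may come from FGF18, radiation, handling or feeding was not tested, and the number of mice per sample is not known.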
